A study of Homo sapiens with 12 samples.

How the data were processed

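RNA was measured in 12 libraries of the human embryonic stem cell line H9 under cardiac differentiation, sequenced on the BGISEQ-500 platform per the series description. The labels place 2 libraries in each of 6 groups, which are DMSO, 60 µM F-53B and 60 µM PFOS at day 8 and at day 12, with the toxicants in the medium from day 0. The labels number the replicates 1 and 2 and say nothing of separate cultures, so p-values measure only the spread between these samples, which may be technical.

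The deposited values are FPKM per gene and library, per the file headers, written with 2 decimals. HISAT, Bowtie2, RSEM and the genome build GRCh38 patch p11 are named in the submitters' processing notes, without versions or an order of steps, and no scaling between libraries is recorded. Each library lists 20042 genes, of which 1002 hold no value in any library, TBXT among them, and 19040 hold values. Of those, 14080 with at least 1 FPKM in at least 2 libraries were tested. Depth is unknown, since only FPKM were used here, and no interval from counts is given.

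Values were taken as log2(FPKM + 1) with no further scaling, and a group-means model of all 12 libraries with 6 residual degrees of freedom was fitted with limma 3.58.1 in R 4.3.3, with robust empirical Bayes moderation and a mean-variance trend. The plan, written before the data were examined, named this test for files that hold FPKM without counts. Adjusted p-values are Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05, and all limma tests are two-sided. The 9 comparisons were these: 4 of a toxicant with DMSO at its day, 2 of F-53B with PFOS, DMSO at day 12 with day 8, and the difference of each toxicant's effect between days. Log2 changes are given with the standard error (SE) of the model. Means are given as FPKM ± SD over 2 libraries, and a fold is the ratio of mean FPKM, so it exceeds the shrunken log2 change for genes near 0. Intervals of the F-53B to PFOS difference are 95% limits from the same model, not corrected for the number of genes.

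Fixed lists of genes, 25 in all, were written from textbook knowledge before the data were examined. They cover cardiomyocyte sarcomere, cardiac transcription factors, cardiac calcium handling and ion channels, epicardial markers, fibroblast and extracellular matrix, smooth muscle markers, epithelial-mesenchymal transition, endothelial markers, blood cell markers, pluripotency, mesendoderm and early mesoderm, endoderm and hepatic, neural and ectoderm, WNT target genes, WNT ligands and receptors, WNT antagonists, BMP and TGF-beta response, retinoic acid response, cell cycle, PPAR targets and fatty acid oxidation, cholesterol synthesis, oxidative stress response, unfolded protein and integrated stress response, p53 response, and oxidative phosphorylation. Each was tested with limma's camera, which compares the list with all other tested genes, at a preset inter-gene correlation of 0.01, and adjusted over all 225 tests of 25 lists in 9 comparisons. Camera with an estimated correlation was run beside it: no list call in any of the 9 comparisons held there, the lowest adjusted p being 0.287, and for each list called in a comparison of a toxicant with DMSO that value was the highest over its alternatives. Fry, also from limma, tests whether the genes of a list move on balance one way and does not compare them with other genes.

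Named genes followed a rule written before the data were examined. It took the 5 largest rises and 5 largest falls among genes past the test with a mean of at least 5 FPKM whose libraries separated by group, up to 3 members per list with the smallest adjusted p, and 10 genes always given: TNNT2, MYH6, MYH7, MYL7, NKX2-5, WT1, TBX18, ALDH1A2, AXIN2 and LEF1. For F-53B against PFOS and for the differences between days, only the largest rises and falls were taken, and for DMSO over time 3 of each with the 10 genes. The text gives part of the genes so named. Results for some list members are not reported here. Other members of the lists that are named were chosen after their values were seen. Copies of near-identical sequence (MYH6 and MYH7, CFC1 and CFC1B, ANXA8 and its copies, the muscle actins ACTA1, ACTA2 and ACTC1, MT1X and MT2A) could exchange reads, so their separate values are less certain. Gene locations are from GENCODE 29 on GRCh38, joined by gene ID and symbol.

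The fit was tested on simulated data. Noise was drawn for each gene separately, so deviations that many genes of a library share were not simulated, and recovery in the real data may be lower. Recovery was taken over changed genes that passed the filter. With 2 libraries per group, it was 90.6% of genes changed by 1 on the log2 scale for day 8 F-53B (13622 genes tested) and 96% for day 8 PFOS (13630 genes). For day 12 it was 97% with F-53B (13623 genes) and 94.9% with PFOS (13620 genes). At a change of 2 the fit recovered 97.9%, 99%, 100% and 99% in the same order, and it called 12, 13, 9 and 14 unchanged genes. Because both toxicants share the DMSO libraries of a day, the correlation of their effects was set beside 20 simulations of unchanged groups, and was taken again with the DMSO libraries of a day split between the toxicants, a check added after the data were seen. Alternatives were median-of-ratios scaling, no low-value filter, a pseudocount of 0.1, the replicate number as a block, only the libraries compared, a fold threshold, and each library left out in turn. Scaling to equal FPKM totals, scaling to totals without the sarcomere list and the 100 most abundant genes, crossed replicate numbers, and the alternatives for lists outside the comparisons of a toxicant with DMSO and for the always-named genes in the difference between days were added after the data were seen. Tests that need counts were not used here.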

Results

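The 12 libraries measured messenger RNA of H9 human embryonic stem cells on the way to cardiomyocytes, with 2 libraries in each of 6 groups: DMSO as the vehicle, F-53B and PFOS, each at day 8 and day 12. F-53B is a chlorinated polyfluorinated ether sulfonate, and PFOS is a perfluoroalkyl sulfonate without the ether oxygen and the chlorine. The series asks about developmental toxicity to the heart, about a turn toward epicardial cells and about WNT signalling. FPKM totals ran from 389249 to 439918 per library, and 12915 to 13292 genes reached 1 FPKM. Replicates correlated across genes with r between 0.989 (day 12 F-53B) and 0.9965 (day 8 F-53B and day 12 DMSO), and genes are not independent replicates.

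The share of all FPKM held by the 22 sarcomere genes set the groups apart. At day 8 it was 2.77% and 3.42% with DMSO, 1.66% and 2.38% with PFOS, and 0.614% and 0.601% with F-53B. At day 12 it was 4.71% and 4.72% with DMSO, 4.27% and 4.01% with PFOS, and 1.24% and 0.641% with F-53B, so the day 12 F-53B replicates stood apart from each other. Between them, 134 genes differed more than 2-fold, against 10 to 39 within the other groups. The first principal component held 61.4% of the variance and the second 21.7%.

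**Figure D1:**
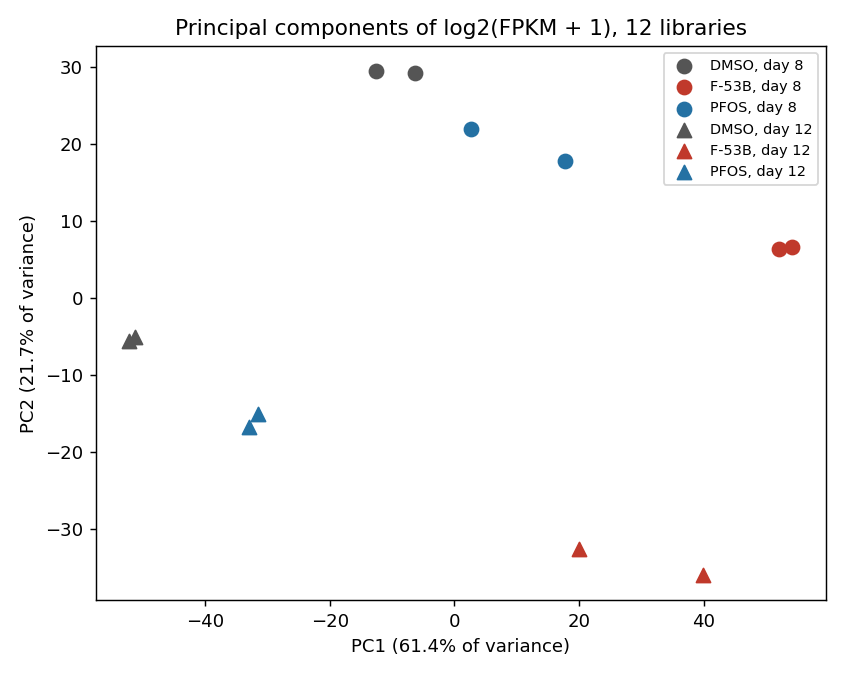
Principal components of the 12 libraries over log2(FPKM + 1) of the tested genes, with 61.4% of the variance on the horizontal axis and 21.7% on the vertical axis. Points are libraries, coloured by treatment and shaped by day.

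Key genes are given with their location on GRCh38. Among sarcomere and cardiac genes, TNNT2 (gene ID 7139), cardiac troponin T, lies on chromosome 1 from 201359008 to 201377762. MYH6 (4624) and MYH7 (4625), the cardiac myosin heavy chains, lie on chromosome 14 from 23381990 to 23408277 and from 23412738 to 23435718. MYL7 (58498), the atrial myosin light chain, lies on chromosome 7 from 44138864 to 44141332. NKX2-5 (1482), a cardiac transcription factor, lies on chromosome 5 from 173232109 to 173235357. The epicardial transcription factors WT1 (7490) and TBX18 (9096) lie on chromosome 11 from 32387775 to 32435630 and on chromosome 6 from 84687351 to 84764519. ALDH1A2 (8854), which makes retinoic acid, lies on chromosome 15 from 57953424 to 58497866. The WNT target AXIN2 (8313) lies on chromosome 17 from 65528563 to 65561647, and LEF1 (51176), both a target and an effector of WNT, lies on chromosome 4 from 108047545 to 108168956. All are protein-coding genes on the minus strand.

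The course of differentiation in DMSO alone sets the background. From day 8 to day 12, MYH7 rose by 3.22 on the log2 scale (SE 0.51, adjusted p = 0.00234), from 14.8 ± 5.14 to 142.3 ± 8.09 FPKM (SD, n = 2 each). TNNT2 (0.59), MYH6 (0.67), MYL7 (0.66) and NKX2-5 (0.72) did not pass the test. AFP, a fetal liver protein, rose by 6.67 (SE 0.36), PENK, the precursor of enkephalin, by 4.59, and S100A14, an epithelial protein, by 4.48. WT1 fell by 2.81 on the log2 scale (SE 0.16, adjusted p = 8.87e-07), from 37 ± 7.74 to 4.36 ± 0.417 FPKM. SHISA3, LCN1 and PRPH, an intermediate filament of neurons, fell by 5.12, 4.69 and 3.77. ALDH1A2 (0.32, adjusted p = 0.179) did not pass, nor did LEF1 (-0.30, adjusted p = 0.12), which passed with only the libraries compared (0.00841). AXIN2 rose by 0.26 (adjusted p = 0.0428), a call lost without any 1 of the 4 libraries (0.0825 to 0.213) and with other scalings (0.0564 to 0.099). Of the 22 sarcomere genes, 12 rose and 10 did not pass the test, with 14 up adjusted over the list alone (median 1.29, adjusted p = 2.44e-05, and adjusted p = 0.506 with an estimated correlation). Of 16 epicardial genes, 2 rose and 9 fell, adjusted over the list alone too (median -0.81, adjusted p = 0.0186, and 0.437 as the adjusted p with an estimated correlation). TBX18 changed by -1.04 (SE 0.25, adjusted p = 0.0116), a call that ended without day 12 DMSO replicate 1 (adjusted p = 0.0671) and with only the libraries compared (0.0787, with alternatives from 0.000265 to 0.0787). Fibroblast and matrix genes fell, 13 of 18 with 3 up, adjusted over the list alone too (median -1.17, adjusted p = 2.44e-05, and adjusted p = 0.287 with an estimated correlation), and so did 14 of 20 cell cycle genes, adjusted over the list alone too (median -0.58, adjusted p = 1.58e-06, and adjusted p = 0.287 with an estimated correlation). Of 14 endoderm and hepatic genes, 10 rose and 1 fell, or 11 and 2 adjusted over the list alone (median 1.59, adjusted p = 0.000308, and adjusted p = 0.432 with an estimated correlation). Of 17 oxidative phosphorylation genes, 15 rose, or 16 adjusted over the list alone (median 0.44, adjusted p = 7.75e-05, and adjusted p = 0.454 with an estimated correlation). In all, 5308 of 14080 genes changed, 2746 up and 2562 down. Without day 12 DMSO replicate 1 the count was 3355, and without replicate 2 it was 3498.

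F-53B at day 8 lowered cardiac genes. MYH6 fell by 6.94 on the log2 scale (SE 0.54, adjusted p = 7.84e-05), from 1148 ± 308 to 8.63 ± 4.05 FPKM (SD, n = 2 each), a 133-fold difference. CKM, the muscle creatine kinase, changed by -6.45 (SE 0.72), NPPA, the atrial natriuretic peptide, by -5.77 (SE 0.47), NKX2-5 by -5.45 (SE 0.55) and MYL4, a light chain of embryonic and atrial muscle, by -5.25 (SE 0.47). Of the 22 sarcomere genes, 21 fell and 1, MYL2, did not pass the test (-0.05). TNNT2 fell by 3.27 (SE 0.36), MYH7 by 3.78 (SE 0.51), TNNI3 by 2.44 (SE 0.22) and MYL7 by 1.79 (SE 0.36). The list's median was -3.52, with 0 up and 21 down also when adjusted over the list alone, and its adjusted p was 1.46e-13, or an adjusted p = 0.329 with an estimated correlation. Of 16 cardiac transcription factors, 4 rose and 11 fell, and the same counts held adjusted over the list alone (median -1.34, adjusted p = 0.000971, and adjusted p = 0.432 with an estimated correlation). MEF2C fell by 3.05 (SE 0.17) and MYOCD, a coactivator of muscle genes, by 3.44 (SE 0.27). Of 19 calcium handling and channel genes, 4 rose and 12 fell, adjusted over the list alone as well, among them RYR2, the calcium release channel (-1.69). That list had a median of -0.86 and an adjusted p = 0.000971, with adjusted p = 0.321 with an estimated correlation.

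Epicardial genes were higher with F-53B at day 8. WT1 rose by 1.68 on the log2 scale (SE 0.16, adjusted p = 3.42e-05), from 37 ± 7.74 to 119.4 ± 4.65 FPKM. TBX18 rose by 1.88 (SE 0.25), TCF21, a transcription factor of epicardium and fibroblasts, by 1.58 (SE 0.15), and UPK3B, a mesothelial membrane protein, by 2.73 (SE 0.26). ALDH1A2 stayed under 1 FPKM in both groups (0.20, adjusted p = 0.386). Of the 16 epicardial genes, 12 rose, 1 fell and 3 did not pass, with 12 and 1 adjusted over the list alone (median 1.06, adjusted p = 6.62e-05, and adjusted p = 0.321 with an estimated correlation). Genes of fibroblasts and matrix went both ways: 13 rose, 4 fell and 1 did not pass, with 13 and 4 adjusted over the list alone (median 0.73, adjusted p = 0.0102, and adjusted p = 0.393 with an estimated correlation). The proteoglycans DCN and LUM rose by 3.26 (SE 0.35) and 3.04 (SE 0.32), SPARC rose by 1.38, and fibronectin, FN1, fell by 1.85 (SE 0.09). ANXA8, an annexin, rose by 2.73 (SE 0.33). ACTA2, smooth muscle actin, fell by 4.15 (SE 0.23) in a smooth muscle list with 3 up and 6 down (median -0.51, adjusted p = 0.144).

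Genes of other lineages also fell with F-53B at day 8. Of 11 endothelial genes, 1 rose and 8 fell, adjusted over the list alone too, among them the junction proteins CDH5 (-2.07, SE 0.18) and ESAM (-1.92, SE 0.17); the median was -1.12, with adjusted p = 0.00198 and adjusted p = 0.322 with an estimated correlation. Of 6 mesendoderm genes, 5 fell, adjusted over the list alone as well (median -0.96, adjusted p = 0.000845, and adjusted p = 0.287 with an estimated correlation), with FGF8 at -3.05 (SE 0.16) and MIXL1 at -1.28 (SE 0.10). Of 14 endoderm and hepatic genes, 1 rose and 10 fell, and 11 fell adjusted over the list alone (median -0.98, adjusted p = 0.000279, and adjusted p = 0.432 with an estimated correlation). SERPINA1, a liver protease inhibitor, fell by 3.98 (SE 0.39), and FOXA2 is listed at 0 in both F-53B libraries. All 17 oxidative phosphorylation genes fell, adjusted over the list alone too (median -0.78, adjusted p = 1.47e-08, and adjusted p = 0.368 with an estimated correlation), such as SDHA (-1.01, SE 0.11). Of 16 PPAR and fatty acid oxidation genes, 11 fell, or 12 adjusted over the list alone (median -0.37, adjusted p = 9.88e-05, and adjusted p = 0.321 with an estimated correlation), with FABP3 at -2.99. Of 15 BMP and TGF-beta response genes, 1 rose and 10 fell, or 11 adjusted over the list alone (median -0.61, adjusted p = 8.25e-05, and adjusted p = 0.287 with an estimated correlation), with BMP7 at -3.10 and BMP2 at -1.86.

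WNT genes at day 8 with F-53B are given by role. AXIN2 (0.19, SE 0.09, adjusted p = 0.115) and LEF1 (0.37, SE 0.14, adjusted p = 0.0551) did not pass the test. LEF1 passed with only the libraries compared (adjusted p = 0.00659) and with both scalings to totals (0.0149 and 0.0335), over alternatives from 0.00659 to 0.258. Of 14 WNT targets, 1 rose and 4 fell, and 4 rose and 4 fell adjusted over the list alone; the median was 0.09, the mean -0.12 and the tested direction down (adjusted p = 0.863). MSX2 fell by 1.78 (SE 0.34) and BAMBI by 0.83 (SE 0.12). Of 21 WNT ligands and receptors, 5 rose and 6 fell (median -0.03, adjusted p = 0.769), with WNT11 at -1.52. Of 9 secreted or membrane WNT antagonists, 6 rose and 1 fell, adjusted over the list alone too (median 0.77, adjusted p = 0.0197, and adjusted p = 0.287 with an estimated correlation): FRZB rose by 3.40 (SE 0.51) and SFRP5 by 1.47 (SE 0.13).

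At day 8 with F-53B, the lists for epithelial-mesenchymal transition (median -0.13, adjusted p = 0.176), blood cells (-0.25, 0.523), pluripotency (-0.19, 0.644), neural and ectoderm (0.23, 0.208), retinoic acid (-0.25, 0.187), cholesterol synthesis (-0.10, 0.661), oxidative stress (0.21, 0.329) and unfolded protein (0.26, 0.329) did not pass. The cell cycle list had a median of 0.25 and an adjusted p of 0.05 at the threshold, with 8 of 20 genes up; it passed with no filter (0.0181), both scalings to totals (0.0364 and 0.0475) and only the libraries compared (0.0165). The p53 list had a median of -0.20 and an adjusted p of 0.076, and passed without day 8 DMSO replicate 1 (adjusted p = 0.046). In all, 6200 genes changed, 3310 up and 2890 down (4098 and 2487 after scaling to equal FPKM totals), of which 1018 by at least 2-fold; leaving out any 1 of the 4 libraries gave 4179 to 4963.

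PFOS at day 8 changed 953 genes, 520 up and 433 down. TXNIP, an inhibitor of thioredoxin, rose by 2.40 on the log2 scale (SE 0.12, adjusted p = 3.75e-06), from 27.5 ± 1.53 to 150.6 ± 24.9 FPKM (SD, n = 2 each), and its relative ARRDC4 rose by 2.24 (SE 0.12), from 3.40 ± 0.141 to 20 ± 3.47. ITGA11, a collagen-binding integrin, rose by 1.58 (SE 0.19) and ACKR3, a chemokine receptor, by 1.58 (SE 0.15). The day 8 F-53B libraries were also above DMSO, with TXNIP at 109.91 and 102.93 FPKM and ARRDC4 at 15.72 and 16.52. ITGA11 (20.19 and 22.48) and ACKR3 (46.83 and 45.04) were higher there than with PFOS, so these rises were not particular to PFOS. With DMSO at day 12, TXNIP had 173.1 and 158.86 FPKM and ARRDC4 17.56 and 18.73, so the day 8 DMSO libraries were the low ones. Both day 8 comparisons rest on these 2 controls. For TXNIP and ARRDC4, a difference of these controls and a rise with both compounds cannot be told apart. TFPI2, a protease inhibitor, fell by 2.21 (SE 0.20). ACTA1, skeletal actin, fell by 2.41 (SE 0.32), a call lost without PFOS replicate 1 (adjusted p = 0.0536, over alternatives from 0.00198 to 0.0536). NPPB, the B-type natriuretic peptide, fell by 2.30 (SE 0.37), a call lost without DMSO replicate 2 (adjusted p = 0.0877) and with only the libraries compared (0.0658, over alternatives from 0.00658 to 0.0877). CFC1B and CFC1, 2 copies of a NODAL co-receptor, fell by 2.54 and 2.33, and without DMSO replicate 2 their adjusted p was 0.143 and 0.17, and with only the libraries compared 0.217 and 0.16. The CFC1 call was also lost with a pseudocount of 0.1 (0.058) and without DMSO replicate 1 (0.0588) and PFOS replicate 1 (0.0697), and the alternatives ran from 2.03e-05 to 0.217 for CFC1B and from 0.0031 to 0.17 for CFC1. ANXA8 rose by 1.52 (SE 0.33), with an adjusted p of 0.125 without DMSO replicate 1, 0.163 without DMSO replicate 2, 0.194 without PFOS replicate 1 and 0.0574 with only the libraries compared, over alternatives from 0.0187 to 0.194. The count was 170 without DMSO replicate 2 and 181 without PFOS replicate 1, and 437 with only the libraries compared. With median-of-ratios scaling 416 genes were up and 528 down, so the balance of directions at day 8 is not settled. Of 60 named genes past the test, 39 lost the call when 1 library was left out.

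No sarcomere gene passed the test one by one with PFOS at day 8. Of the 22 sarcomere genes, 0 passed, also adjusted over the list alone, against 953 of all 14080 tested genes past the same test. At that rate few of 22 genes would pass, so the count of 0 does not set the list apart. The model's spread is shared by all 6 groups, so a missed call does not show a lack of effect. TNNT2 was at -0.64 (SE 0.36, adjusted p = 0.34), MYH6 at -1.33 (SE 0.54, 0.199), MYH7 at -0.78 (0.417), MYL7 at -0.50 (0.463) and NKX2-5 at -1.24 (0.235). The list as a whole was lower (median -0.63, adjusted p = 7.5e-06), which did not hold at an adjusted p = 0.478 with an estimated correlation or with fry (0.248). Of 19 calcium handling and channel genes, 1 rose and 5 fell, and 4 and 7 adjusted over the list alone (median -0.46, adjusted p = 0.00263, and adjusted p = 0.322 with an estimated correlation). The cardiac transcription factors had a median of -0.24 (adjusted p = 0.141), with 2 up and 1 down, and passed with only the libraries compared (0.02).

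Markers of other lineages moved with PFOS at day 8. Of 11 endothelial genes, 5 fell, and 1 rose and 7 fell adjusted over the list alone (median -0.50, adjusted p = 2.55e-06, and adjusted p = 0.287 with an estimated correlation); CDH5 fell by 1.87 (SE 0.18, adjusted p = 0.000717) and ESAM by 1.66 (SE 0.17). CD34 and TAL1, genes of blood and endothelial progenitors, fell by 2.12 (SE 0.22) and 1.36 (SE 0.15) in a list of 5 (median -0.03, adjusted p = 0.0408, and adjusted p = 0.322 with an estimated correlation) whose call was lost without DMSO replicate 1 (0.0543) and PFOS replicate 2 (0.0511), with median-of-ratios scaling (0.0631) and with no filter (0.13). Of 6 mesendoderm genes, 4 fell, or 5 adjusted over the list alone (median -0.64, adjusted p = 7.22e-07, and adjusted p = 0.287 with an estimated correlation): EOMES by 1.40, FGF8 by 1.29 and MIXL1 by 0.76. GDF3, a factor of pluripotent cells, fell by 1.87 (SE 0.19). Of 14 endoderm genes, 3 fell, and 1 rose and 8 fell adjusted over the list alone (median -0.49, adjusted p = 0.000971, and adjusted p = 0.454 with an estimated correlation), with FOXA2 at -1.27 (SE 0.19). In the neural list, DCX, a microtubule protein of young neurons, rose by 0.92 (SE 0.13; list median 0.10, adjusted p = 0.147).

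Epicardial, matrix and signalling lists also had calls with PFOS at day 8. Of 16 epicardial genes, 3 rose, or 4 adjusted over the list alone: TBX18 (1.16, SE 0.25), TCF21 (0.95, SE 0.15) and WT1 (0.73, SE 0.16). All 3 calls were lost without DMSO replicate 2 (adjusted p = 0.0883, 0.0647 and 0.194) and without PFOS replicate 1 (0.203, 0.0565 and 0.204), and those of TBX18 and WT1 also with only the libraries compared (0.217 and 0.0903), over alternatives from 0.00142 to 0.217, 0.00355 to 0.0647 and 0.0125 to 0.204. The list median was 0.20 (adjusted p = 0.0349, and adjusted p = 0.462 with an estimated correlation), and its call was lost without DMSO replicate 2 (0.0738) and PFOS replicate 1 (0.141). ALDH1A2 was at 0.13. Of 18 fibroblast and matrix genes, 9 rose and 1 fell, and 10 and 2 adjusted over the list alone (median 0.37, adjusted p = 0.00254, and adjusted p = 0.344 with an estimated correlation), with FN1 at -0.73 (SE 0.09). The WNT antagonists had 3 of 9 up, or 4 adjusted over the list alone (median 0.43, adjusted p = 0.0022, and adjusted p = 0.287 with an estimated correlation). AXIN2 (0.12, adjusted p = 0.496) and LEF1 (0.40, adjusted p = 0.125) did not pass, but LEF1 passed with only the libraries compared (0.0466, over alternatives from 0.0466 to 0.421). The WNT targets had a median of -0.10 (adjusted p = 0.285) and the ligands and receptors 0.02 with a mean of -0.11 (adjusted p = 0.0838). Of 15 BMP and TGF-beta genes, 5 fell, or 10 adjusted over the list alone (median -0.47, adjusted p = 4.23e-08, and adjusted p = 0.287 with an estimated correlation).

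Further lists passed with PFOS at day 8 at small medians. They were smooth muscle (-0.27, adjusted p = 0.0251, and adjusted p = 0.322 with an estimated correlation; 1 up and 2 down, or 1 and 3 adjusted over the list alone), with TAGLN at -0.83 (SE 0.11), and retinoic acid response (-0.22, adjusted p = 0.0049, and adjusted p = 0.287 with an estimated correlation; 1 up and 3 down, or 2 and 4 adjusted over the list alone), with CRABP1 at -0.96 (SE 0.12). The PPAR list (-0.12, adjusted p = 0.0352, and adjusted p = 0.454 with an estimated correlation; 1 down, or 2 adjusted over the list alone) lost its call without DMSO replicate 2 (0.0983) and PFOS replicate 1 (0.146). Oxidative phosphorylation (-0.14, adjusted p = 0.00384, and adjusted p = 0.563 with an estimated correlation; 0 of 17 genes past the test, also adjusted over the list alone) lost it without PFOS replicate 1 (0.47). The lists for epithelial-mesenchymal transition (median 0.10, mean -0.01, adjusted p = 0.908), pluripotency (median 0.06, mean -0.11, 0.78), oxidative stress (-0.10, 0.321), unfolded protein (-0.08, 0.392) and p53 (0.06, 0.631) did not pass. The cell cycle list (0.10, 0.0667) passed without PFOS replicate 2 (adjusted p = 0.036), with no filter (0.0383) and with only the libraries compared (0.02), and cholesterol synthesis (0.15, 0.144) passed without DMSO replicate 1 (adjusted p = 0.00465).

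At day 12, F-53B raised most epicardial and matrix genes. SFRP2, a secreted WNT antagonist, rose by 6.84 on the log2 scale (SE 0.36, adjusted p = 1.07e-06), from 0.245 ± 0.177 to 154.2 ± 88.5 FPKM (SD, n = 2 each). UPK3B rose by 5.24 (SE 0.26), PTGS1, a cyclooxygenase, by 4.54 (SE 0.31), ITLN1, a mesothelial lectin, by 4.52 (SE 0.21) and ALDH1A2 by 4.49 (SE 0.18), the last from 0.62 ± 0.0707 to 36.4 ± 12.2 FPKM. WT1 rose by 4.08 (SE 0.16, adjusted p = 4.84e-08), from 4.36 ± 0.417 to 90.1 ± 17.8 FPKM, and TBX18 by 3.21 (SE 0.25). Mean WT1 with F-53B was 119.4 FPKM at day 8, while DMSO went from 37 to 4.36, so the larger day 12 change goes with the fall in DMSO. Of 16 epicardial genes, 14 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone (median 3.23, adjusted p = 7.76e-08, and adjusted p = 0.287 with an estimated correlation). Of 18 fibroblast and matrix genes, 17 rose and 1 fell, adjusted over the list alone too (median 1.89, adjusted p = 1.97e-07, and adjusted p = 0.287 with an estimated correlation). COL3A1, a fibrillar collagen, rose by 2.54 (SE 0.11), COL6A3 by 2.28 (SE 0.11) and PDGFRB, a receptor of mesenchymal cells, by 1.89 (SE 0.08).

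Sarcomere genes were below DMSO with F-53B at day 12, though some stood above their day 8 F-53B values. With F-53B, MYH6 had 11.49 and 5.76 FPKM at day 8 and 212.04 and 71.08 at day 12. TNNT2 had 143.14 and 136.87, then 584.85 and 259.56. TNNI1 (102.43 and 101.7, then 124.32 and 81.15) and MYL7 (978.49 and 934.77, then 1450.57 and 650.76) stood above the day 8 values in replicate 1 only. The step between days within F-53B was not tested. Against DMSO at day 12, all 22 fell, also adjusted over the list alone (median -3.05, adjusted p = 1.33e-09, and adjusted p = 0.394 with an estimated correlation). MYL2, the ventricular light chain, fell by 3.80 (SE 0.21), MYH7 by 4.36 (SE 0.51), MYH6 by 3.85 (SE 0.54), TNNT2 by 2.38 (SE 0.36) and MYL7 by 2.43 (SE 0.36). NKX2-5 fell by 3.68 (SE 0.55), from 140.9 ± 12 to 12.2 ± 10.3 FPKM, the wide SD reflecting replicates that stood apart. Cardiac transcription factors had 4 up and 10 down, adjusted over the list alone too (median -0.70, adjusted p = 0.067), and passed without F-53B replicate 1 (adjusted p = 0.00452) and with equal FPKM totals (0.0474). GATA4 rose by 0.78 (SE 0.09) while PROX1 fell by 2.20 (SE 0.17). Of 19 calcium handling and channel genes, 5 rose and 12 fell, or 13 adjusted over the list alone (median -1.35, adjusted p = 0.0224, and adjusted p = 0.393 with an estimated correlation). KCNJ3 and KCNA5, potassium channels of the atrium, rose by 2.13 and 1.21. The natriuretic peptide NPPB fell by 5.39 (SE 0.37).

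**Figure D2:**
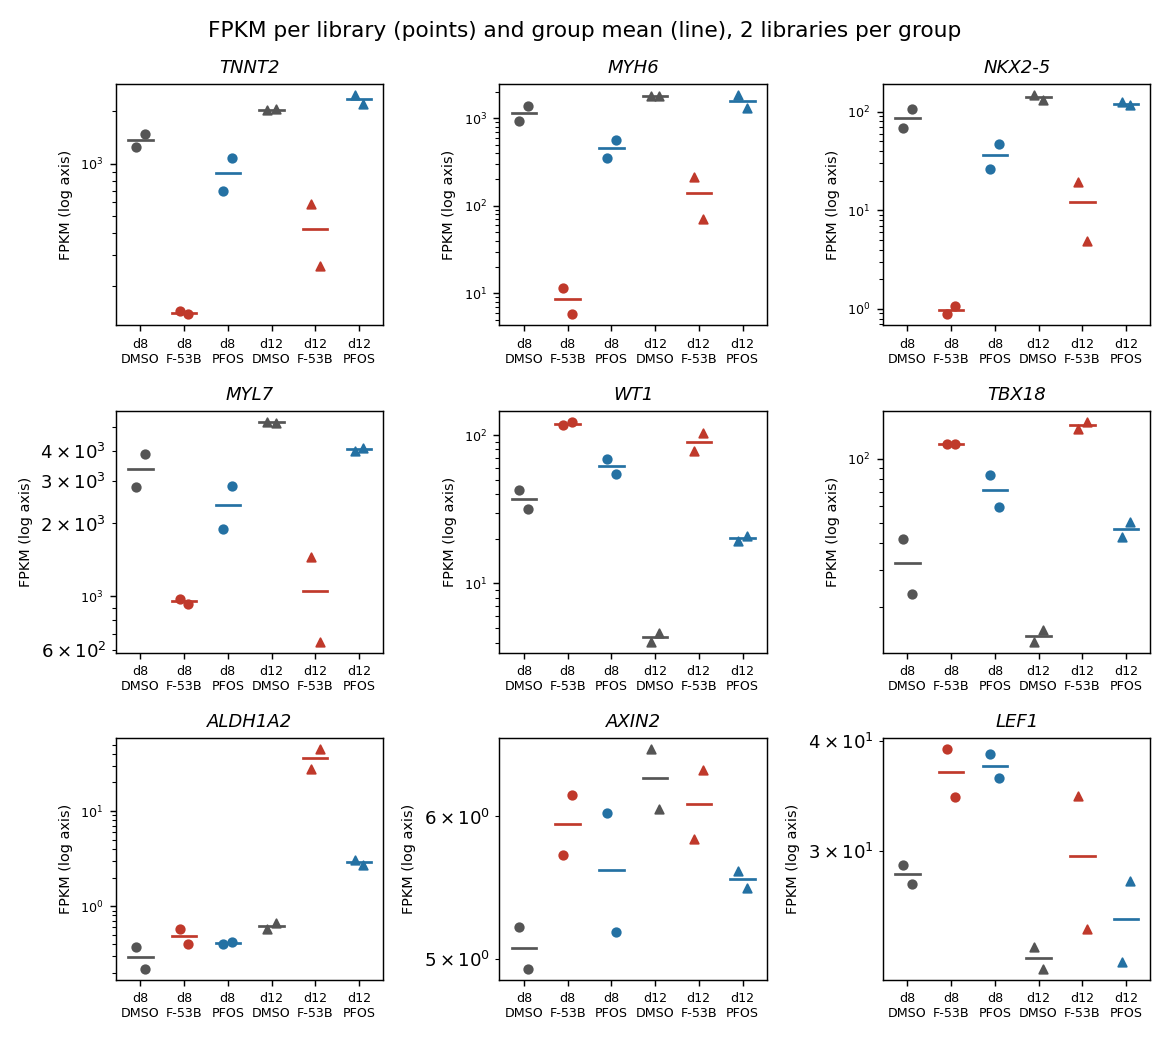
FPKM of marker genes in each of the 12 libraries on a log axis, by treatment and day, with 1 point per library and a line at the group mean. WT1 stands at 4.36 FPKM with DMSO and 90.1 FPKM with F-53B at day 12, and MYH6 at 1790 and 141.6 FPKM.

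Endoderm and metabolic genes fell at day 12 with F-53B. TTR, a carrier of thyroid hormone, fell by 5.86 on the log2 scale (SE 0.60), SERPINA1 by 5.46 (SE 0.39) and AFP by 5.42 (SE 0.36), and S100A14, outside the list, by 5.07 (SE 0.23). All 14 endoderm and hepatic genes fell, also adjusted over the list alone (median -2.23, adjusted p = 2.14e-07, and adjusted p = 0.322 with an estimated correlation). Of 18 cholesterol synthesis genes, 14 fell, also adjusted over the list alone (median -0.98, adjusted p = 1.16e-06, and adjusted p = 0.322 with an estimated correlation), with the regulator SREBF2 at -1.46 (SE 0.10). All 17 oxidative phosphorylation genes fell, also adjusted over the list alone (median -0.96, adjusted p = 1.61e-07, and adjusted p = 0.389 with an estimated correlation), with SDHA at -1.57 (SE 0.11). In the PPAR list 1 rose and 14 fell, adjusted over the list alone too (median -0.56, adjusted p = 0.000279, and adjusted p = 0.322 with an estimated correlation): ANGPTL4 rose by 1.31 (SE 0.14) and CPT1A fell by 1.72 (SE 0.19). Of 6 mesendoderm genes, 5 fell, adjusted over the list alone too (median -0.81, adjusted p = 0.00901, and adjusted p = 0.321 with an estimated correlation). Of 11 endothelial genes, 2 rose and 8 fell, or 9 adjusted over the list alone (median -0.67, adjusted p = 0.0416, and adjusted p = 0.437 with an estimated correlation), a call lost without F-53B replicate 2 (0.0526).

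WNT genes at day 12 with F-53B follow in the same order. AXIN2 (-0.04, SE 0.09, adjusted p = 0.734) did not pass, nor did LEF1 (0.35, SE 0.14, adjusted p = 0.0572). LEF1 passed with both scalings to totals (0.021 and 0.0312) and without F-53B replicate 2 (0.0025), over alternatives from 0.0025 to 0.502. Of 14 WNT targets, 1 rose and 5 fell, or 1 and 4 adjusted over the list alone (median -0.13, adjusted p = 0.308), while fry gave an adjusted p of 0.000569. MSX2 fell by 3.06 (SE 0.34), TNFRSF19 fell by 1.36 (SE 0.09) and LGR5 rose by 0.76 (SE 0.14). Ligands and receptors had 8 up and 7 down (median 0.03, adjusted p = 0.76), with WNT2B at 2.35, the receptor FZD7 at 1.61 and WNT5B at -1.85. Of 9 antagonists, 7 rose and 1 fell, adjusted over the list alone too (median 0.87, adjusted p = 0.00552, and adjusted p = 0.287 with an estimated correlation), with SFRP5 at 3.78 (SE 0.13).

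Several lists at day 12 with F-53B held members that moved apart. Pluripotency had 4 up and 3 down (median -0.06, mean -0.02, tested direction up, adjusted p = 0.769), with DPPA4 at 1.59 and LEFTY2 at -2.24. Smooth muscle had 4 up and 3 down (median -0.14, mean -0.07, direction up, 0.949), epithelial-mesenchymal transition 4 and 4 (median 0.05, mean -0.01, direction up, 0.886), retinoic acid response 4 and 4 (median -0.22, mean -0.18, direction up, 0.969) and BMP and TGF-beta 5 and 6 (median -0.15, 0.794). Blood cells (-0.15, 0.618), oxidative stress (0.34, 0.173) and unfolded protein (0.15, 0.72) did not pass. Cell cycle (median -0.09, 0.105) passed without DMSO replicate 1 (adjusted p = 0.0237), and the neural list (0.81, 0.0838) passed without F-53B replicate 2 (0.0438). The p53 list (-0.24, 0.0514) had 6 of 11 down, with GDF15 at -1.77 (SE 0.11) and CDKN1A, an inhibitor of cell division, at -1.29 (SE 0.13), and passed without DMSO replicate 1 (0.0393) and without F-53B replicate 2 (0.0344). In all, 7913 genes changed, 3970 up and 3943 down, of which 1807 by at least 2-fold; leaving out any 1 library gave 6349 to 7280, with 7280 without F-53B replicate 1.

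At day 12, PFOS also raised epicardial genes, with sarcomere genes mostly not past the test. SFRP2 rose by 2.72 on the log2 scale (SE 0.36, adjusted p = 0.00214), UPK3B by 2.21 (SE 0.26), SFRP5 by 2.20 (SE 0.13), SMOC2, a matrix protein, by 2.05 (SE 0.16) and WT1 by 1.98 (SE 0.16, adjusted p = 6.43e-05), the last from 4.36 ± 0.417 to 20.1 ± 0.976 FPKM (SD, n = 2 each). TBX18 rose by 1.61 (SE 0.25), ALDH1A2 by 1.26 (SE 0.18), BNC1, a zinc finger factor of mesothelium, by 1.75 (SE 0.19) and TCF21 by 1.33 (SE 0.15). Of 16 epicardial genes, 11 rose, 1 fell and 4 did not pass, or 12 and 1 adjusted over the list alone (median 1.18, adjusted p = 9.07e-09, and adjusted p = 0.287 with an estimated correlation). Of 18 fibroblast and matrix genes, 9 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 0.71, adjusted p = 2.82e-05, and adjusted p = 0.287 with an estimated correlation), with COL3A1 at 1.29 (SE 0.11) and PDGFRB at 0.93 (SE 0.08).

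Of the 22 sarcomere genes, 2 fell with PFOS at day 12, also adjusted over the list alone: MYL2 by 2.38 (SE 0.21) and CSRP3, a muscle LIM protein, by 2.28 (SE 0.47). The CSRP3 call was lost without DMSO replicate 1 (0.0863), DMSO replicate 2 (0.121) and PFOS replicate 1 (0.113) and with a pseudocount of 0.1 (0.0554), over alternatives from 2.33e-05 to 0.121. The list's median was -0.38 (adjusted p = 0.00409, and adjusted p = 0.63 with an estimated correlation). The model's spread is shared by all 6 groups, and the day 12 F-53B replicates differed over this list by a median of 1.31 on the log2 scale. Calls missed here may therefore rest on the spread of groups outside this comparison and do not show a lack of effect. TNNT2 (0.19, adjusted p = 0.774), MYH6 (-0.19, 0.859) and NKX2-5 (-0.22, 0.845) did not pass. MYH7 (-1.34, 0.141) and MYL7 (-0.37, 0.567) did not either, but passed with only the libraries compared (0.000178 and 0.00355, the lowest over alternatives up to 0.372 and 0.738). NPPB fell by 4.08 (SE 0.37), from 116.6 ± 5.47 to 6.11 ± 1.92 FPKM, and ACTA1 by 2.78 (SE 0.32), the latter call lost with a pseudocount of 0.1 (adjusted p = 0.0501, over alternatives from 0.000297 to 0.0501). NPPA fell by 2.45 (SE 0.47), a call lost without DMSO replicate 1 (0.0796), DMSO replicate 2 (0.0894) and PFOS replicate 1 (0.0966), over alternatives from 0.00509 to 0.0966. Cardiac transcription factors had 2 up and 2 down (median -0.05, mean -0.06, direction up, adjusted p = 0.897), with TBX5 at 0.43 and HAND2 at 0.39, and channels 2 up and 3 down (median -0.25, 0.274).

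Most endoderm and cholesterol genes, and 4 of 11 p53 response genes, fell with PFOS at day 12. S100A14 fell by 4.35 on the log2 scale (SE 0.23, adjusted p = 4.98e-06), from 36.8 ± 14.2 to 0.785 ± 0.134 FPKM. TTR fell by 3.04 (SE 0.60), a call lost without DMSO replicate 1 (0.104), DMSO replicate 2 (0.0593) and PFOS replicate 1 (0.105), over alternatives from 0.0075 to 0.105. Of 14 endoderm genes, 9 fell, or 13 adjusted over the list alone (median -0.99, adjusted p = 3.6e-09, and adjusted p = 0.321 with an estimated correlation). Of 18 cholesterol genes, 11 fell, or 13 adjusted over the list alone (median -0.43, adjusted p = 1.61e-07, and adjusted p = 0.321 with an estimated correlation). Of 11 p53 response genes, 4 fell, or 5 adjusted over the list alone (median -0.22, adjusted p = 0.000279, and adjusted p = 0.287 with an estimated correlation): GDF15 by 1.65 (SE 0.11) and CDKN1A by 1.28 (SE 0.13). Of 6 mesendoderm genes, 2 fell, or 4 adjusted over the list alone (median -0.41, adjusted p = 0.00129, and adjusted p = 0.287 with an estimated correlation). The cell cycle list (median -0.13, adjusted p = 0.00921, and adjusted p = 0.432 with an estimated correlation; 2 down, also adjusted over the list alone) lost its call without DMSO replicate 2 (0.207) and PFOS replicate 2 (0.144). The BMP and TGF-beta list (-0.19, adjusted p = 0.0331, and adjusted p = 0.431 with an estimated correlation; 1 up and 4 down, or 1 and 5 adjusted over the list alone) lost it without DMSO replicate 1 (0.0552) and PFOS replicate 1 (0.242).

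WNT genes at day 12 with PFOS are given by role. AXIN2 (-0.16, SE 0.09, adjusted p = 0.301) and LEF1 (0.13, SE 0.14, adjusted p = 0.596) did not pass. Of 14 WNT targets, TNFRSF19 alone passed, also adjusted over the list alone, and fell by 0.99 (SE 0.09; list median -0.11, adjusted p = 0.0907, fry 0.00373). The list passed with only the libraries compared (adjusted p = 0.0422). Of 9 antagonists, 4 rose, also adjusted over the list alone (median 0.15, adjusted p = 0.0147, and adjusted p = 0.287 with an estimated correlation), a call lost without PFOS replicate 2 (0.0537); SFRP1 rose by 0.62 (SE 0.09). Ligands and receptors had 4 up and 2 down (median -0.05, mean 0, adjusted p = 0.908), with FZD1 at 1.04 and FZD5 at -1.10.

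The other lists did not pass with PFOS at day 12. Those were epithelial-mesenchymal transition (median 0.06, mean -0.08, adjusted p = 0.782), blood cells (median 0.05, mean 0, direction down, 0.861), pluripotency (median 0.04, mean 0, direction down, 0.979), neural (0.06, 0.515), retinoic acid (-0.14, 0.588), PPAR (-0.07, 0.524), oxidative stress (median -0.03, mean 0.11, direction down, 0.871) and oxidative phosphorylation (-0.13, 0.123). Smooth muscle (-0.18, 0.0564) passed without DMSO replicate 1 (0.0393) and PFOS replicate 1 (0.011), endothelial markers (-0.21, 0.0886) without PFOS replicate 1 (0.0281), and unfolded protein (-0.10, 0.0548) without DMSO replicate 2 (0.0334) and PFOS replicate 1 (0.0369). With only the libraries compared, endothelial (0.0417), smooth muscle and oxidative phosphorylation lists (both 0.0358) passed too. With no filter, smooth muscle and unfolded protein did (both 0.0474), as did unfolded protein with both scalings to totals (0.0387 and 0.0457). In the unfolded protein list ATF3, a stress-induced factor, fell by 1 on the log2 scale (SE 0.09) and PHGDH, an enzyme of serine synthesis, rose by 0.66 (SE 0.11). In all, 1730 genes changed, 939 up and 791 down, or 683 up and 1003 down after scaling to equal FPKM totals. The count was 657 without DMSO replicate 1, 583 without DMSO replicate 2 and 810 without PFOS replicate 1. Of 69 named genes past the test, 36 lost the call when 1 library was left out.

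**Figure D3:**
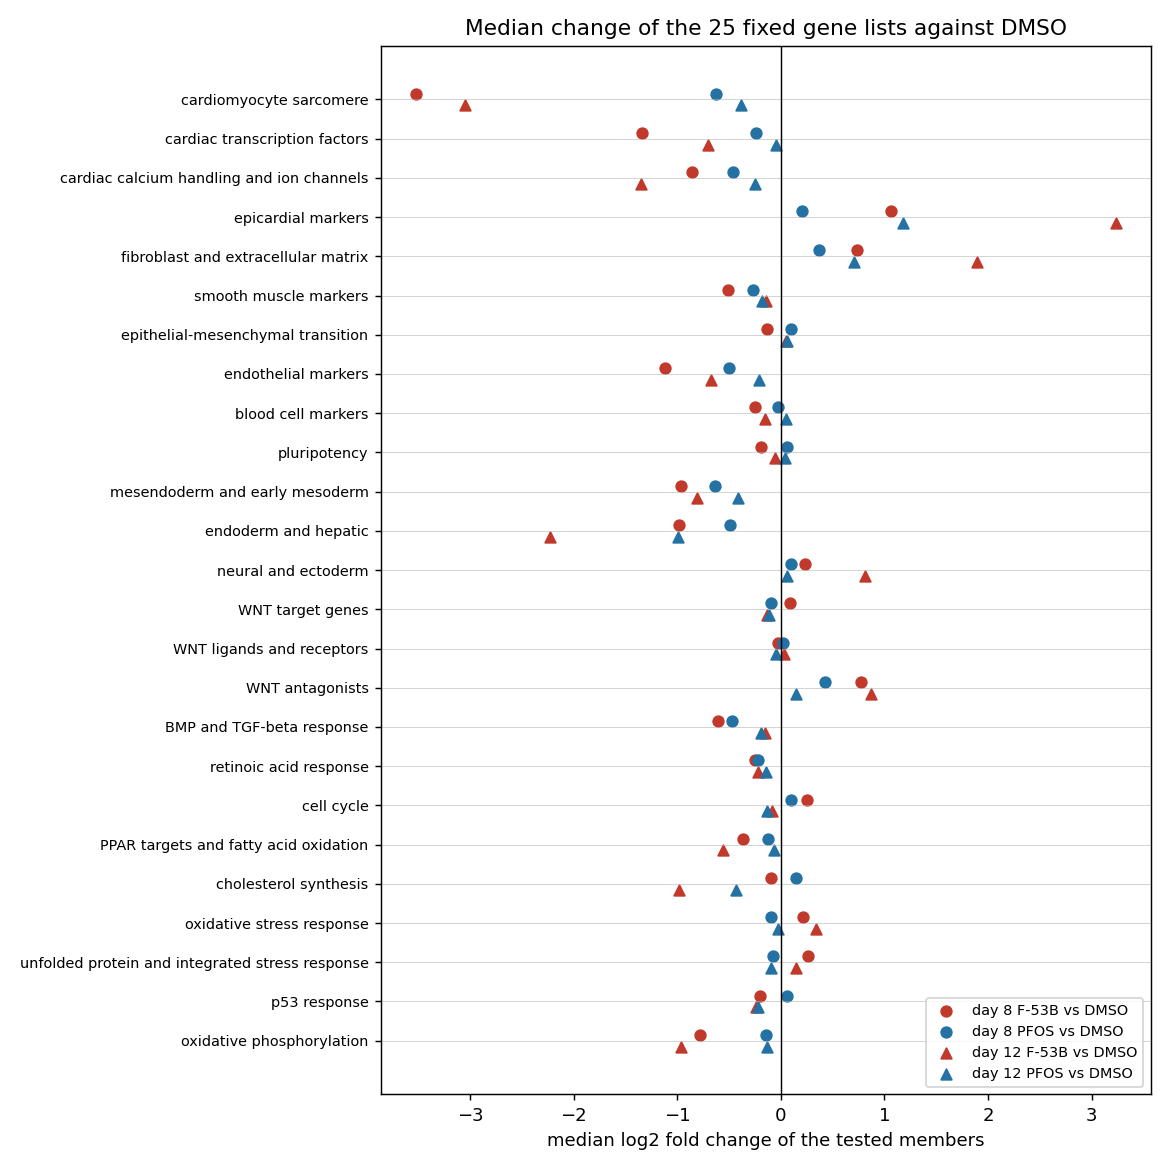
Median log2 change of each fixed list, in 4 comparisons of a toxicant with DMSO; the horizontal axis is log2 fold change, with red for F-53B, blue for PFOS, circles for day 8 and triangles for day 12. The epicardial list stands at 3.23 with F-53B and 1.18 with PFOS at day 12, and the sarcomere list at -3.05 and -0.38.

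F-53B and PFOS were compared directly at the matched dose and day. At day 8, MYH6 was lower with F-53B than with PFOS by -5.61 on the log2 scale (SE 0.54, adjusted p = 0.00104), CKM by -5.49, MYL3 by -5.21, TNNC1 by -4.52 and MYL4 by -4.40. Of the 22 sarcomere genes, 21 were lower with F-53B, also adjusted over the list alone (median -2.57, adjusted p = 4.02e-15, and adjusted p = 0.322 with an estimated correlation). All 17 oxidative phosphorylation genes were lower with F-53B, adjusted over the list alone too (median -0.59, adjusted p = 7.8e-09, and adjusted p = 0.359 with an estimated correlation). Of 16 epicardial genes, 9 were higher, or 10 adjusted over the list alone (median 0.68, adjusted p = 2.91e-05, and adjusted p = 0.321 with an estimated correlation). MELTF, an iron-binding membrane protein, was higher with F-53B by 1.87 (SE 0.16), and CRHR2, a receptor of urocortins, by 1.80 (SE 0.26). NPNT was higher by 1.98, SFRP2 by 1.87 and DCN by 1.79, but these 3 calls were lost without PFOS replicate 2 (adjusted p = 0.162, 0.0621 and 0.0685). NPNT also lost it without F-53B replicate 1 (0.0932), F-53B replicate 2 (0.145) and PFOS replicate 1 (0.0519), and DCN without F-53B replicate 2 (0.0546). Their alternatives ran from 0.00153 to 0.162, 0.00277 to 0.0621 and 0.00173 to 0.0685. WT1 differed by 0.95 (95% interval 0.58 to 1.31), while TBX18 (0.73, 0.15 to 1.30, adjusted p = 0.0603), CDH5 (-0.20, -0.59 to 0.19), CD34 (-0.44, -0.92 to 0.04), GDF3 (-0.34, -0.77 to 0.08) and EOMES (-0.12, -0.45 to 0.21) were not shown to differ. For AXIN2 (0.07, -0.13 to 0.28) and LEF1 (-0.03, -0.34 to 0.29) the interval excludes a difference of 1. In all 3991 genes differed, 1875 higher and 2116 lower with F-53B, or 2508 and 1730 after scaling to equal FPKM totals. The count was 2019 without F-53B replicate 1, 1482 without F-53B replicate 2 and 1191 without PFOS replicate 2.

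At day 12 the compounds differed in cardiac and epicardial genes alike. SFRP2 was higher with F-53B than with PFOS by 4.12 on the log2 scale (SE 0.36, adjusted p = 4.26e-05), ITLN1 by 3.31, ALDH1A2 by 3.23, UPK3B by 3.03 and ANXA8 by 2.96. SERPINA1 was lower by -4.48 (SE 0.39), AFP by -4.14, CKM by -4.00, IRX4, a ventricular transcription factor, by -3.80 and MYH6 by -3.66. Of 16 epicardial genes, 13 were higher and 1 lower with F-53B, adjusted over the list alone too (median 1.86, adjusted p = 3.48e-07, and adjusted p = 0.287 with an estimated correlation). Of 22 sarcomere genes, 21 were lower, or 22 adjusted over the list alone (median -2.64, adjusted p = 9.39e-10, and adjusted p = 0.393 with an estimated correlation). All 17 oxidative phosphorylation genes were again lower with F-53B, adjusted over the list alone too (median -0.77, adjusted p = 2.06e-08, and adjusted p = 0.368 with an estimated correlation), and 16 of 18 fibroblast and matrix genes were higher and 1 lower, adjusted over the list alone too (median 1.04, adjusted p = 1.61e-07, and adjusted p = 0.287 with an estimated correlation). The compounds were not shown to differ in CDKN1A (-0.01, 95% interval -0.29 to 0.28, adjusted p = 0.965), GDF15 (-0.12, -0.37 to 0.13), ATF3 (0.22, 0.01 to 0.43, adjusted p = 0.0746), GCLC (-0.15, -0.37 to 0.06), AXIN2 (0.12, -0.09 to 0.32) or LEF1 (0.22, -0.10 to 0.53). In all 6742 genes differed, 3362 higher and 3380 lower with F-53B, or 4107 and 2773 after scaling to equal FPKM totals.

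Effects of the compounds went in like directions across genes. At day 8, 462 genes were higher and 401 lower with both, against 122.2 and 88.9 for independent calls, and 5 went opposite ways. At day 12 the counts were 827, 640 and 37, against 264.8 and 221.5. The correlation across genes was 0.76 and 0.693, where simulated unchanged groups sharing the DMSO libraries gave 0.494 and 0.503, and the covariance was 0.129 and 0.164 against 0.0101 and 0.0103. The simulations gave 0 shared calls, which sets no reference for these counts, since groups without change yield few calls for either toxicant. With the DMSO libraries of a day split, so that each toxicant was set against a different one, in both ways, the correlation was 0.652 and 0.67 at day 8 and 0.641 and 0.657 at day 12, and the covariance 0.126 and 0.112, then 0.156 and 0.16. At day 8 the split gave 208 or 25 genes higher and 197 or 37 lower with both, against 35.3 or 4.1 and 33.3 or 5.6 for independent calls, and at day 12 it gave 305 or 296 genes higher and 199 lower with both, against 72.4 or 68.5 and 49.8 or 51.7. Over genes called with F-53B, the slope of PFOS on F-53B changes was 0.343 at day 8 and 0.284 at day 12.

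**Figure D4:**
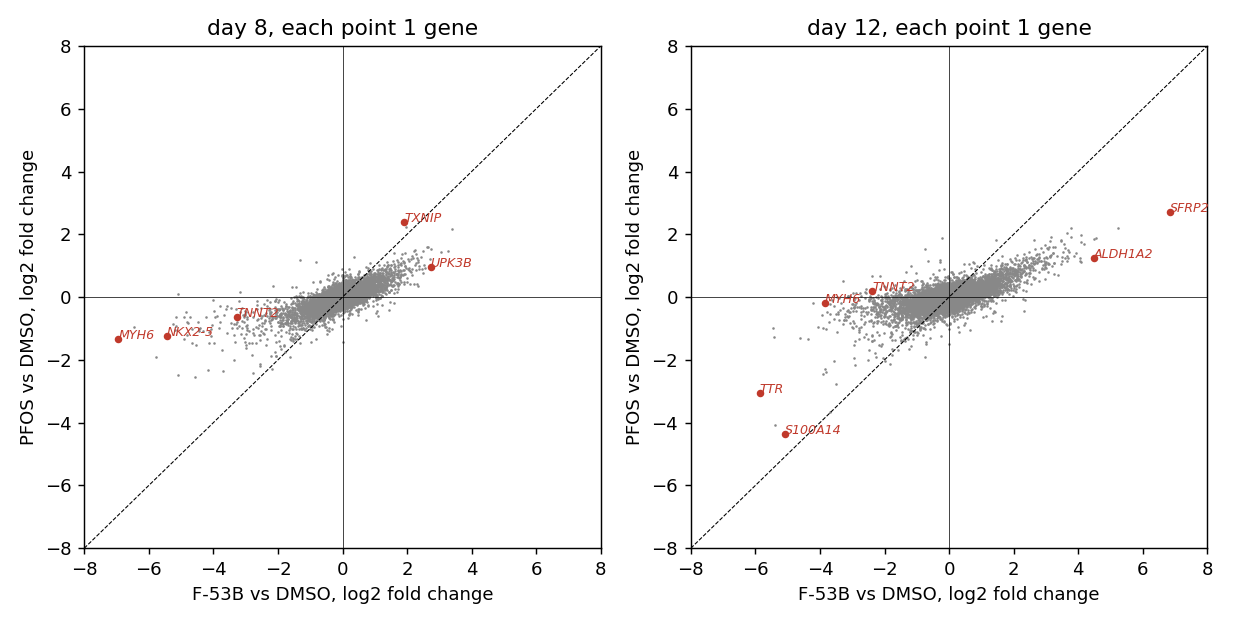
Log2 changes with PFOS against those with F-53B, each against DMSO of the same day, with 1 point per tested gene. Correlations across genes are 0.76 at day 8 and 0.693 at day 12.

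Whether an effect differed between days was tested as the difference of the changes. For F-53B, SFRP2 had a day 12 effect larger by 4.54 on the log2 scale (SE 0.50, adjusted p = 0.00064), ALDH1A2 by 4.29 (SE 0.25, adjusted p = 3.6e-06) and WT1 by 2.40 (SE 0.23). The fall of MYH6 was smaller at day 12 by 3.09 (SE 0.77, adjusted p = 0.0348), a call lost without any 1 of the day 8 DMSO, day 8 F-53B or day 12 DMSO libraries (0.051 to 0.117) and with only the libraries compared (0.0604), over alternatives from 0.00731 to 0.117. TNNT2 (0.88, adjusted p = 0.294), MYH7 (-0.58, 0.645), AXIN2 (-0.23, 0.264) and LEF1 (-0.02, 0.958) were not shown to differ. Without day 12 F-53B replicate 2 the TNNT2 difference was 1.47, and without replicate 1 that of MYH7 was -1.43. With a pseudocount of 0.1 the MYH7 difference turned to 1.47 (limma adjusted p = 0.316). MYH7 had 0.16 and 0.08 FPKM with F-53B at day 8, near the floor, so the direction of its difference between days is not settled. For PFOS, TXNIP differed by -2.27 (SE 0.17, adjusted p = 0.000147), and ARRDC4 by -2.23 (SE 0.17). Their day 12 changes were 0.13 and 0.02, as DMSO itself went from 27.5 to 166 FPKM for TXNIP while PFOS had 150.6 at day 8 and 181.7 at day 12, and from 3.40 to 18.1 FPKM for ARRDC4. S100A14 had 0.4 and 0.91 FPKM with DMSO at day 8, near the floor, so a fall at that day could only be small. S100A14 differed by -3.96 (SE 0.33) and WT1 by 1.25 (SE 0.23, adjusted p = 0.0293), a call lost without any 1 of 6 of the 8 libraries (0.0626 to 0.121, over alternatives from 0.0183 to 0.121). The F-53B effect differed in 2306 genes, 1317 up and 989 down. Without day 8 F-53B replicate 1 or 2 the count was 1412 or 1374, and without day 12 DMSO replicate 1 or 2 it was 1427 or 1326. The PFOS effect differed in 198 genes, 86 up and 112 down, or 73 and 161 after scaling to equal FPKM totals. That count was 120 and 101 without day 8 DMSO replicate 1 and 2, 122 without day 8 PFOS replicate 1, 60 and 59 without day 12 DMSO replicate 1 and 2, 68 without day 12 PFOS replicate 1 and 339 without day 12 PFOS replicate 2.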

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

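The results of this part came up because a test of the difference between days 8 and 12 passed for the effect of a toxicant. All tests of an explanation were chosen after the pattern was seen, except that the bounds of the immediate-early test were set before its values; the first bound of the test on the day 12 DMSO libraries was met, and it was reworded after the values were seen, because the design cannot separate the explanations.

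The effect of F-53B differed between the days in 2306 genes. List medians of the difference, day 12 less day 8, were 1.76 for epicardial (adjusted p = 4.42e-09), 1.03 for fibroblast and matrix (1.32e-08), -1.15 for endoderm and hepatic (7.81e-05), 0.55 for BMP and TGF-beta (3.64e-05), 0.44 for retinoic acid response (0.0353), -0.33 for cell cycle (1.98e-06) and -0.83 for cholesterol synthesis (7.82e-11). None of these 7 held with an estimated correlation, where the lowest adjusted p was 0.287. Among genes, the difference was 4.54 for SFRP2, 4.29 for ALDH1A2, 3.94 for ITLN1, 3.85 for NPY, 3.45 for ACTA2, 3.09 for MYH6, 2.40 for WT1 and 1.33 for TBX18 (adjusted p = 0.0354). It was -4.40 for S100A14, -4.10 for AFP, -3.21 for NPPB, -3.02 for PENK and -2.91 for APOA1. With DMSO at day 8, S100A14 (0.4 and 0.91 FPKM) and AFP (1.53 and 1.67) were near the floor, so only a small fall was possible then. With DMSO at day 12 they had 46.8 and 26.78, and 311.89 and 221.88, so their differences go with the rise in DMSO. The MYH6 call (0.0348) was lost without any 1 of 6 libraries (0.051 to 0.117) and with only the libraries compared (0.0604), and the TBX18 call without any 1 of the day 8 F-53B, day 12 DMSO or day 12 F-53B libraries (0.0507 to 0.108) and with equal FPKM totals (0.0508). The retinoic acid list lost its call without day 8 DMSO replicate 2 (0.0973), day 8 F-53B replicate 1 (0.0504) and day 12 DMSO replicate 2 (0.0546), and with no filter (0.098).

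The effect of PFOS differed between the days in 198 genes. List medians of the difference were 0.68 for epicardial (adjusted p = 5.15e-07), 0.22 for fibroblast and matrix (0.00641), 0.65 for endothelial (0.00384), -0.56 for endoderm and hepatic (0.00706), 0.23 for BMP and TGF-beta (0.0122), 0.21 for retinoic acid response (0.0296), -0.24 for cell cycle (6.9e-05), -0.40 for cholesterol synthesis (4.42e-09) and -0.28 for p53 response (5.14e-05), and none held with an estimated correlation, where the lowest adjusted p was again 0.287. Among genes, it was 2.58 for NPY, 1.63 for TFPI2, 1.55 for PLVAP, 1.53 for SFRP5, 1.48 for DPEP1 and 1.25 for WT1. It was -3.96 for S100A14, again with day 8 DMSO near the floor, -2.27 for TXNIP, -2.23 for ARRDC4, -2.02 for PRSS35 and -1.90 for ITGA11. Calls for 5 of these 11 genes were lost when 1 library was left out. NPY (adjusted p = 0.0485, alternatives 0.00532 to 0.179) lost it without any 1 of the day 8 PFOS (0.12 and 0.117), day 12 DMSO (0.141 and 0.179) and day 12 PFOS libraries (0.159 and 0.0534), with other scalings (0.0512 to 0.0514) and with only the libraries compared (0.0534). TFPI2 (0.024, alternatives 0.00549 to 0.108) lost it without day 8 DMSO replicate 1 (0.0607) or 2 (0.0904), day 8 PFOS replicate 1 (0.0555), day 12 DMSO replicate 1 (0.0927) or 2 (0.108), and day 12 PFOS replicate 1 (0.0857) or 2 (0.0546). DPEP1 (0.0272, alternatives 0.0061 to 0.117) lost it without day 8 DMSO replicate 1 (0.0653), day 12 DMSO replicate 1 (0.0946) or 2 (0.117), and day 12 PFOS replicate 1 (0.113), and ITGA11 (0.0082, alternatives 0.00213 to 0.0545) without day 12 PFOS replicate 1 (0.0545). WT1 (0.0293, alternatives 0.0183 to 0.121) lost it without day 8 DMSO replicate 1 (0.0685), day 8 PFOS replicate 2 (0.079), day 12 DMSO replicate 1 (0.121) or 2 (0.0851), and day 12 PFOS replicate 1 (0.106) or 2 (0.0626). Of the lists, endoderm and hepatic lost its call without day 8 DMSO replicate 1 (0.35), day 8 PFOS replicate 2 (0.0993) and day 12 DMSO replicate 1 (0.0644), BMP and TGF-beta without 3 libraries (0.0783 to 0.148) and retinoic acid without 3 (0.0619 to 0.126), while fry gave 0.0767 for fibroblast and matrix, 0.226 for endoderm and hepatic and 0.114 for BMP and TGF-beta.

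With F-53B, sarcomere genes fell while epicardial genes rose. Scaling to totals without sarcomere and abundant genes left the epicardial median at 3.25 (lower quartile 1.74). Its factors ran only from 0.9768 to 1.036, so this scaling could not have removed the rise and decides nothing by itself. The sarcomere list held at most 4.72% of all FPKM in a library. That share is too small for its loss to raise other genes this much, which argues against totals closed over lost sarcomere transcripts. A lower share of cardiomyocytes would raise all other cell types, but the endoderm and hepatic list had a median of -2.23 (quartiles -4.29 and -1.27) while the epicardial quartiles were 1.72 and 4.08. The 14 epicardial genes that rose did so with an interquartile range of 2.15, so more cells of the epicardial kind and a higher expression per cell cannot be told apart from whole-culture RNA, where other cells share some of these genes. A change in the mix of cells therefore stays open beside a change within cells.

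The day 12 F-53B replicates differed in sarcomere genes by a median of 1.31 on the log2 scale (quartiles 1.16 and 1.56). Admixture of the day 12 DMSO kind in replicate 1 would need a median of 12.96% for sarcomere genes (quartiles 10.81 and 17.17) but only 1.07% for 9 endoderm and hepatic genes (quartiles 0.54 and 1.90), which argues against it. The scaling factors of the replicates differ by 0.0168 on the log2 scale, far under the difference. Over all 952 genes of this kind the median was 14.14% (quartiles 8.06 and 20.4), so cardiomyocytes without endoderm, or a less complete response in replicate 1, stay open. No biological explanation was tested.

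At day 12, 35 of 69 genes at least 2-fold lower with both toxicants fell by like sizes (within 0.5), against 4 of 122 that were higher with both. They include GDF15, CDKN1A, HNF4A and CLDN4, and 28 of the 35 rose in DMSO from day 8 to day 12 past the test, by a median of 1.08 over the 35, while their median moved by 0.03 with F-53B and -0.01 with PFOS. A handling stress in the DMSO cultures would lower immediate-early genes in both comparisons. Of 17 such genes 8 rose and 2 fell with F-53B (median 0.27). With PFOS 0 rose and 4 fell (median -0.06, adjusted p = 0.0718 with camera). These medians met the bound set against such a stress over the list. They do not exclude it, since F-53B may itself raise some of these genes, and the PFOS calls all went down. NR4A1 (-0.89 and -1.05) and SOCS3 (-0.33 and -0.64) fell with both. ATF3, outside this list, had 13.5 and 16.38 FPKM with DMSO at day 12, 8.05 and 8.39 with F-53B, and 7.14 and 6.69 with PFOS. The 2 DMSO libraries differed over the 35 genes by a median of 0.19. A shared technical difference of these libraries and a rise held back by both compounds cannot be told apart, since both comparisons rest on the same 2 controls.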

How the results depend on the processing

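No named gene reversed its direction past the threshold, and no list did in the 4 comparisons of a toxicant with DMSO or, in a check added after the data were seen, in the other 5, but the balance of genes up and down did turn with scaling in several comparisons; for example, median-of-ratios gave 416 up and 528 down for day 8 PFOS, and equal totals gave 683 and 1003 for day 12 PFOS and 2508 and 1730 for F-53B against PFOS at day 8. Equal totals, totals without abundant and sarcomere genes, crossed numbers, split controls and ratios over all members called were added after the data were seen. Over the named genes and other lists, 5044 values kept their side of the threshold, 329 lost it and 59 gained it, with 222 of the losses from leaving out 1 library. A lone library left in a group is taken to vary like the other groups. The cause of changes was not tested, except that a fold threshold leaves fewer calls by construction. A count-based test tool and a second unit were not run, since the files hold only FPKM, and without counts the limit set by depth is unknown.

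Requiring at least 2-fold left 1018 genes for day 8 F-53B, 120 for day 8 PFOS, 1807 for day 12 F-53B and 215 for day 12 PFOS, 436 and 1119 for F-53B against PFOS at days 8 and 12, 787 for DMSO over time, and 605 and 81 for the differences between days with F-53B and PFOS. Only the libraries compared gave 437 for day 8 PFOS. With each library left out in turn, counts were 170 to 956 for day 8 PFOS, 583 to 2024 for day 12 PFOS, 1191 to 3717 for F-53B against PFOS at day 8, 3355 to 3936 for DMSO over time, 1326 to 2413 for the F-53B difference between days and 59 to 339 for the PFOS one.

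With an estimated correlation, the adjusted p of the sarcomere list was 0.329 for day 8 F-53B, 0.478 for day 8 PFOS, 0.394 for day 12 F-53B and 0.63 for day 12 PFOS, and of the epicardial list 0.321, 0.462, 0.287 and 0.287. Fry, which tests the list without other genes, gave 0.248 and 0.321 for the sarcomere list with PFOS at days 8 and 12, and 0.0725 for the epicardial list with PFOS at day 8, whose adjusted p ran from 0.00938 to 0.141 with a library left out. For WNT targets fry gave lower values, 0.000569 for day 12 F-53B and 0.00373 for day 12 PFOS, and only the libraries compared gave 0.0422 for the latter.

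Replicate numbers only number the samples: deviations of same-numbered libraries correlated at -0.132 to 0.139. With a replicate block, counts were 5976, 819, 7734 and 1578 for F-53B and PFOS at day 8 and day 12, 3683 and 6580 for F-53B against PFOS, 5012 for DMSO over time, and 2094 and 156 for the differences between days. The block ended the WT1 call for the PFOS difference between days (0.0526). With crossed numbers the block gave 6132 for day 8 F-53B, 3866 and 6746 for F-53B against PFOS at days 8 and 12, and 4968 for DMSO over time.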

Other observations

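Tests of hypotheses in this part were made on lists chosen after some of their genes were seen. The bounds for the hypoxia, FGF and epithelial lists were set before their values. The test of 1 ratio was chosen after the result.

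Some glycolytic genes, chosen after their values were seen, were lower with F-53B. ALDOA, an aldolase, fell by 2.10 on the log2 scale at day 12 (adjusted p = 0.000333), from 892.45 to 214.78 FPKM (n = 2 each), ENO1, an enolase, by 1.82, PGK1, a phosphoglycerate kinase, by 1.57 and PFKP, a phosphofructokinase, by 2.34. At day 8, ALDOA fell by 1.86, ENO1 by 1.74 and PGK1 by 1.36; the list was not tested at that day, and HK2 (0.24), PFKL (0.06) and SLC2A1 (-0.05) did not pass. At day 12, HK2 (-0.78), PFKL (-0.17) and SLC2A1 (-0.41) did not pass either. With PFOS at day 12 the same 4 genes were at 0.05, 0.27, 0.06 and -0.23, and none passed the test. PFKFB3, which promotes glycolysis, rose by 0.37 with F-53B at day 12.

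A lower hypoxia and glycolysis programme with F-53B at day 12 was the first hypothesis, from LDHA, BNIP3 and ENO3, which were left out of the list. Of 28 genes, 18 fell and 1 rose, with a median of -0.82 (quartiles -1.68 and -0.48, adjusted p = 3.92e-05 over 6 tests, and adjusted p = 0.352 with an estimated correlation). The values fit the hypothesis, though glycolytic genes are also abundant in cardiomyocytes, so a change in the mix of cells may give the same fall.

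Lower FGF and ERK feedback with PFOS at day 8 was the second, from ETV4, ETV5, SPRY4 and FGF8, also left out. Of 18 genes, 3 rose and 1 fell, with a median of -0.20 (quartiles -0.35 and 0.05, adjusted p = 0.0405, and adjusted p = 0.352 with an estimated correlation), which missed the bound of -0.25 and decides nothing. EPHA2, an ephrin receptor, fell by 0.53 and PHLDA1 rose by 0.45.

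A loss of epithelial transcripts with both toxicants at day 12 was the third, from S100A14, KRT7 and CLDN4. With PFOS 7 of 17 genes fell and 0 rose, with a median of -0.44 (adjusted p = 2.68e-06, and adjusted p = 0.18 with an estimated correlation). With F-53B 6 rose and 6 fell, with a median of 0.02 (adjusted p = 0.721). ESRP1, a splicing factor of epithelia, rose by 1.39 with F-53B, and AP1M2, an epithelial sorting adaptor, fell by 1.30 with PFOS. The F-53B values show no loss over this list as a whole, as members go both ways, so a loss with both toxicants was not shown. By its bounds the hypothesis stays undecided, since the bound against it had to be met with both toxicants.

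That PFOS acts as a smaller amount of F-53B, with 1 ratio of effects for all gene groups, was the fourth, and ratios of PFOS to F-53B changes at day 12 were taken over genes called with F-53B with a mean over 5 FPKM in each day 12 group, a floor chosen after the data were seen. The median was 0.08 over 19 sarcomere genes (0.06 to 0.11 with each library left out), 0.37 over 14 fibroblast and matrix genes (0.33 to 0.40), 0.39 over 14 cholesterol genes (0.34 to 0.46), 0.13 over 16 oxidative phosphorylation genes (0.06 to 0.18) and 0.43 over 5 epicardial genes (0.40 to 0.46). Without the floor it was 0.13 over 22 sarcomere genes (0.11 to 0.17), 0.33 over 18 fibroblast and matrix genes (0.30 to 0.34) and 0.34 over 15 epicardial genes (0.31 to 0.38). Quartiles of the sarcomere and fibroblast lists overlap, narrowly with the floor (0.01 to 0.20 and 0.17 to 0.49) and more without it (0.03 to 0.25 and 0.12 to 0.47), while those of the cholesterol list (0.30 to 0.55) lie above the sarcomere ones. A first bound on the sarcomere and fibroblast quartiles was met by 1 ratio, and a second one chosen after that was not. With all bounds required together the test stays undecided. The values themselves argue against 1 ratio for the sarcomere, oxidative phosphorylation and cholesterol lists. They do not bear on whether PFOS acts as a smaller amount of F-53B without 1 ratio, since each compound was given at 1 dose. Sarcomere quartiles with and without the floor, and oxidative phosphorylation quartiles with it (0.01 to 0.15), lie under the cholesterol ones (0.30 to 0.55). Ranges with each library left out do not overlap between the cholesterol list and either of the others. For the sarcomere and fibroblast lists the quartiles overlap, though these ranges do not.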
